A study of Mus musculus with 12 samples.

How the data were processed

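RNA from laser-microdissected mucosa was measured on 12 arrays, 3 for each of colon knockout, colon floxed, ileum knockout and ileum floxed mucosa of C57BL6/J mice. Per the labels, the mice were untreated male littermates of 4 to 6 weeks, the RNA was amplified with a kit for picogram amounts of RNA and labelled with biotin, and mucosa was dissected from sections of colon or ileum. The labels disagree on the tissue in a single place, where a field names sectioned tumours as the source while the titles, the tissue field and the design name mucosa, so the samples are treated as mucosa. The labels do not say whether colon and ileum samples of the same number come from the same mouse, or that the samples of a group come from separate mice beyond their numbers. The p-values therefore measure the spread between these samples, which may be technical in part, and if regions share animals the p-values of knockout against floxed averaged over both tissues may be too small and those between regions too large.

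The deposited table holds log2 expression values, and per the submitters' processing notes RMA and Partek were used, with no version, role or order given. RMA as a method corrects background, normalizes arrays to a common distribution and summarises probes, and which of these steps was applied at which level is not given in the sources used here. The table had 725678 rows, of which 437027 were probe selection regions (parts of exons), 282044 were exon junctions and 6607 were controls. Its values ran from 0.701 to 14.1, and the medians of the 12 arrays from 3.77 to 3.87, while their interquartile ranges ran from 2.82 to 3.10. No further normalization was applied to the values reported. No detection call was used here, and folds against values near background understate differences. No genome was used, so no coordinates are given.

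Rows were named through the platform annotation, which gave 1 gene symbol to 580167 rows, several to 18694 and none to 120210. Only rows with 1 symbol entered gene values. Of 31383 symbols in the annotation 29760 were current, 1584 were updated through a table of current mouse gene names and 39 were kept as given. The value of a gene was the median of its rows in each array, over a median of 11 rows, and 7532 genes had 1 row. This gave 31276 genes, all of which were tested. A median over exons and junctions describes a gene's overall level and can hide changes in a few exons, so rows were also tested singly. Rows of near-identical genes can share signal, and single members of such families are reported as uncertain.

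Samples were grouped by their titles. A mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), which left 8 residual degrees of freedom plus 4.72 from the prior. The contrasts were knockout against floxed in the colon, in the ileum and averaged over both tissues, the interaction of genotype and tissue, and ileum against colon in each genotype. P-values were two-sided, adjusted with the Benjamini-Hochberg method over all genes of a contrast, and called at 0.05. Gene lists were tested with limma's camera function at a preset correlation between genes of 0.01 and adjusted over the 34 lists of a contrast, with a correlation estimated from the data as an alternative, and members were also adjusted over the list alone. The lists covered cell types of the mucosa, neighbouring tissues that could be mixed in, metabolic and stress pathways, and genes known to respond to the receptor, from textbook knowledge. Of their 597 genes 38 were not analysed here. Means of lists per array were compared between groups with exact permutation tests, which cannot give less than 0.1 for 3 arrays against 3. Each list's median was set against 10000 random lists of the same size drawn from 50 bins of brightness.

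The genes named for each contrast followed a fixed rule. It took Ppard and S100a4, then the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose groups did not overlap, filled with the genes of smallest p where fewer passed, and then up to 4 members of smallest p of each list that passed, or of the 3 lists of smallest p where fewer than 3 passed (up to 3 members of each of 6 lists for the regional contrasts). Predicted genes, small RNAs, olfactory and related receptors and immune receptor segments were counted and not named. The test of the lists, the lists, the naming rule, the contrasts and the alternatives named below as chosen beforehand were set before the data were examined. Members of lists beyond this rule, such as Enpep, Sis, Mttp, Dpp4, Aqp8, Slc51b, Abcc2, Slc2a1, Pfkl, Hk1, Idi1, Lyz1, Reg3a, Guca2a, Olfm4, Sox9, Gstm1, Prdx6, Sult1a1, Adh1 and Slc15a1 in the regional contrasts, were named because they passed, after their values had been seen.

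The precision of arrays is limited by their number. Simulated data had normal noise at each gene's moderated limma spread, with 100 genes changed per size among 31276. The fit recovered 73% of 2-fold and 98% of 4-fold changes in the colon contrast, 65% and 100% in the ileum contrast and 93% and 100% over both tissues. It recovered 22% and 96% in the interaction, 70% and 99% in the regional contrast of floxed mice and 66% and 98% in that of knockout mice. Among unchanged genes it called 8, 10, 17, 6, 9 and 4 in these contrasts. In each contrast 10 of 10 simulated lists shifted by 0.5 were called, and of 10 unchanged lists 1 was called in the interaction, 1 in the regional contrast of floxed mice, 1 in the regional contrast over both genotypes and 0 in the others. The simulated genes varied independently, and these lists were called at an unadjusted camera p under 0.05. The counts therefore do not give the rate of false calls for real lists, whose genes move together. The recovered shares hold for this number of changed genes and for noise without outlying arrays. With fewer changed genes the adjusted threshold is stricter, so fewer 2-fold changes would be recovered.

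Background was taken from control rows of known base composition, as the mean log2 value of rows with 15 to 25 G or C bases of 25, and the median of all negative control rows was compared beside it. These rows were read from the same processed values as the genes. If arrays were brought to a common distribution, higher bright genes can go with lower control rows. Background is therefore not independent of the gene values it was used to adjust. The alternatives chosen beforehand were the mean or the brightest row in place of the median, the brighter part of the genes only, quantile normalization, median centring, a trended and robust variance, array weights, a fold minimum of 1.5, a replicate block, the compared groups only, and leaving out each array. Alternatives added after the data were seen were array background as a covariate, probe selection regions only, both first knockout arrays left out, both second floxed arrays left out, leaving out arrays for the lists and for the difference of list means, random lists, and the regional contrast over both genotypes with families of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.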

Results

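Gene expression was measured in the mucosa of the colon and of the ileum of male mice that were 4 to 6 weeks old and had received no treatment. The knockout mice carried a floxed gene for PPARβ/δ (Ppard, a nuclear receptor for fatty acids) and a Cre recombinase driven by the promoter named FSP, for fibroblast-specific protein 1, whose gene is S100a4. Their floxed littermates served as controls. The mucosa had been cut from stained sections with a laser microdissection microscope, and its RNA was hybridised to an array that covers exon regions and exon junctions. The 12 arrays fell into 4 groups of 3 arrays each, namely colon knockout, colon floxed, ileum knockout and ileum floxed. Values of 31276 genes were compared on the log2 scale. The correlation across genes between arrays of the same group, in which genes are not independent replicates, ranged from 0.954 to 0.979. The number of arrays per group limits the precision of every value. Values below are the mean ± SD of the 3 arrays of a group unless another number is given, and adjusted p-values are two-sided limma p-values after Benjamini-Hochberg adjustment over all genes.

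The targeted gene was measured first, as a check of the labels. Ppard had a log2 value of 6.88 ± 0.43 in colon knockout mucosa and 6.74 ± 0.15 in colon floxed mucosa, a difference of 0.15 with a standard error of 0.20 and a 95% interval from -0.29 to 0.59 (adjusted p = 0.89). In the ileum it was 6.78 ± 0.17 in knockout and 6.39 ± 0.21 in floxed mucosa, a difference of 0.39 with a 95% interval from -0.06 to 0.83 (adjusted p = 0.711). Ppard was represented by 23 array rows, and their knockout minus floxed differences ran from -1.14 to 0.71 in the colon and from -0.63 to 1.11 in the ileum. None of the 23 passed the threshold in either tissue over 719071 rows tested with limma, and none was lower in both tissues at an unadjusted p under 0.05. The lowest difference in each tissue belonged to the same junction row, a dim row with a mean of 3.26. Its unadjusted limma p was 0.0212 in the colon and 0.167 in the ileum. Knockout and floxed arrays did not overlap for 1 lower row, this one, and 1 higher row in the colon. In the ileum this held for 1 lower row, a different one, and 2 higher rows. The labels do not state which exons the floxed allele removes, so a row outside the deleted part checks nothing. The Cre promoter is named for fibroblasts, and the measured tissue was mucosa. S100a4, the gene whose promoter names the Cre line, was near the median gene, at 3.43 ± 0.24 in colon knockout, 3.86 ± 0.33 in colon floxed, 3.61 ± 0.71 in ileum knockout and 3.43 ± 0.49 in ileum floxed mucosa. Its knockout minus floxed difference was -0.43 in the colon (adjusted p = 0.844) and 0.18 in the ileum (adjusted p = 0.897).

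**Figure D1:**
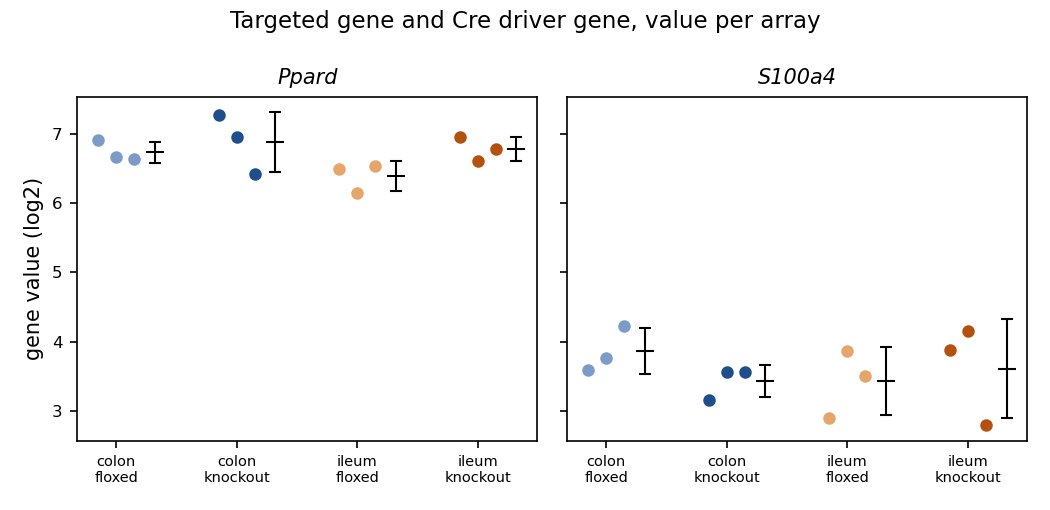
Gene values (log2, vertical axis) of Ppard and S100a4 in each array by group (horizontal axis), with dots for the 3 arrays of a group and a cross and bar for their mean ± SD. Ppard lay between 6.15 and 7.27 in all 12 arrays, with overlapping knockout and floxed arrays in the colon and no lower value in knockout ileum.

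The question of the first comparison was how colon mucosa differs when the receptor gene is targeted with the fibroblast-named Cre. The 15 measured genes of the goblet cell list, whose products are made by the mucus-secreting cells of the epithelium, all had positive knockout minus floxed differences, with a median of 0.51 on the log2 scale. Ang4, an antimicrobial ribonuclease, was at 6.02 ± 0.40 in knockout and 4.71 ± 1.05 in floxed colon (difference 1.30), and the tissue kallikrein Klk1 at 9.71 ± 0.73 and 8.89 ± 0.53 (difference 0.82). Of 33 oxidative phosphorylation genes, 29 had positive differences (median 0.50), among them the succinate dehydrogenase subunits Sdhd (0.71), Sdhb (0.77) and Sdha (0.65) and the complex I subunit Ndufa9 (0.80). No single gene passed its test.

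The colon genes with the smallest p-values among those with a higher mean in knockout mucosa were Ddt (0.73), Ap1s3 (0.72), Hsd17b13 (0.84), Psmb2, a proteasome subunit (0.90), Bend3 (0.67), Mospd3 (0.70), Atp1b3, a subunit of the sodium pump (0.76), and Med9, a subunit of the Mediator complex (1.06). Med9 was at 6.21 ± 0.17 in knockout and 5.16 ± 0.48 in floxed colon, 2.08-fold. Those with a lower mean were Rasl11a (-0.71), Rfpl4b (-0.67), Ly6g6c (-0.66), the interleukin-1 family gene Il1f10 (-0.91), the secretoglobin Scgb1a1 (-0.69), Lin7a (-0.78), Morn2 (-0.88) and Klhl23 (-0.53). Each of these 16 genes separated the 3 knockout from the 3 floxed arrays and had an adjusted p of 0.844, so none is reported as changed. Several were dim, such as Rfpl4b (1.69 in knockout and 2.37 in floxed colon), Lin7a (2.28 and 3.05), Klhl23 (2.43 and 2.96) and Scgb1a1 (2.66 and 3.34). The median of all negative control rows was 2.924 in knockout and 2.935 in floxed colon arrays. Groups of 3 and 3 do not overlap by chance in 10% of genes.

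As sets tested against all other genes with camera, 13 of 34 gene lists rose in knockout colon and 0 fell, while 0 members of any list passed over all genes and 0 when adjusted over the list alone. None of these calls held with an estimated correlation (adjusted p = 0.607 for each list with an estimated correlation, except adjusted p = 0.663 for cell cycle genes). With the preset correlation, oxidative phosphorylation (adjusted p = 5.19e-07), goblet cell (1.61e-06), xenobiotic metabolism (0.000171, 19 of 24 members positive, with Ugt2b5 at 0.70 and Cyp4f14 at 0.81) and cholesterol synthesis (0.000199, 13 of 14 positive, with Fdps at 0.74 and Sc5d at 0.94) had the smallest p-values. The list of genes known as PPARβ/δ targets, most of them enzymes of fatty acid oxidation, also rose (0.00024, 18 of 20 positive, median 0.34), with Hadhb at 0.67, Ech1 at 0.52, Ucp2 at 0.47 and Acadvl at 0.34. The difference of its list mean was 0.322, which became 0.151 without colon knockout 1 and 0.024 (95% interval from -0.370 to 0.418) at equal array background. The antioxidant response list (0.000199, with Txn1 at 0.80), the interferon response (0.00228, with Oas2 at 0.52), glycolysis (0.00228, with Gapdh at 0.98), tight junctions (0.00234), antioxidant enzymes (0.0055), the unfolded protein response (0.0055), fibroblast and matrix genes (0.0216) and cell cycle genes (0.0422) completed the 13. The rise went together with a measured property of the arrays, since the background control rows with 15 to 25 G or C bases of 25, called array background below, averaged 6.518 ± 0.223 in colon knockout and 6.804 ± 0.186 in colon floxed arrays (two-sided exact permutation p = 0.2, where 0.1 is the smallest possible). The median of all negative control rows was 2.924 ± 0.048 and 2.935 ± 0.059 (two-sided exact permutation p = 0.9). Both measures come from the same processed values as the genes and are not independent of them.

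In limma 0 of 31276 genes passed in the colon, with 1494 genes at an unadjusted p under 0.05 where 1564 were expected by chance and a smallest adjusted p of 0.844. The 13 lists became 3 without colon knockout 1, 6 without colon floxed 2, and 1, which fell, when array background was a covariate. Without colon knockout 1 the difference of the list mean went from 0.436 to 0.211 for oxidative phosphorylation, from 0.465 to 0.230 for xenobiotic metabolism, from 0.305 to 0.129 for the antioxidant response and from 0.232 to 0.087 for antioxidant enzymes. It also went from 0.325 to 0.159 for the interferon response, from 0.261 to 0.102 for the unfolded protein response, from 0.250 to 0.142 for glycolysis, from 0.15 to 0.058 for fibroblast and matrix genes and from 0.173 to 0.043 for cell cycle genes. Colon floxed 2 stood apart from the other arrays on the third principal component, at -48.8 with the others from -13.0 to 11.7. Without it the difference became 0.265 for xenobiotic metabolism, 0.15 for the interferon response, 0.141 for PPARβ/δ targets, 0.073 for fibroblast and matrix genes and 0.15 in place of 0.253 for tight junctions. Cholesterol synthesis went from 0.308 to 0.167 without colon knockout 2 and cell cycle genes to 0.112 without colon floxed 3. Without colon knockout 3 the difference grew, to 0.543 for the interferon response, 0.469 for the antioxidant response and 0.427 for the unfolded protein response. It also grew to 0.364 for antioxidant enzymes, 0.291 for cell cycle genes and 0.245 for fibroblast and matrix genes. Without colon floxed 1 it grew to 0.382 for tight junctions and 0.461 for the antioxidant response. Of the 13 lists only goblet cell genes kept their difference within 1.5 times whichever array was left out.

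In the ileum, all 33 oxidative phosphorylation genes had positive knockout minus floxed differences (median 0.55), as had all 16 Paneth cell and antimicrobial genes (median 0.90) and all 11 smooth muscle genes (median 0.55). The cytochrome oxidase subunits Cox7a2 and Cox5b each had a difference of 0.97 and Cox6a1 one of 0.47. Lyz1, the lysozyme of Paneth cells at the crypt base, was at 8.09 ± 1.43 in knockout and 6.69 ± 0.76 in floxed ileum (1.40), with Pla2g2a at 1.60, Reg3a at 1.62 and the protease Mmp7 at 0.98. The smooth muscle actin gene Acta2 was at 7.50 ± 1.01 and 6.45 ± 0.46 (1.05), with Myh11 at 0.77, Flna at 0.62 and Des at 0.55. In ileum knockout 1 alone Lyz1 was at 9.59, Reg3a at 8.88 and Pla2g2a at 7.36, and without that array the difference of the list mean went from 0.919 to 0.345 for Paneth cell genes, from 0.591 to 0.317 for oxidative phosphorylation, from 0.581 to 0.251 for smooth muscle genes and from 0.552 to 0.316 for goblet cell genes. No single gene passed its test here either.

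Among the ileum genes with a higher mean in knockout mucosa, the smallest p-values belonged to Speer9-ps1 (1.08), the mitochondrial rhomboid protease Parl (0.90), Gins4 (0.81), Tm2d1 (0.95), Sumo3 (0.57), Obi1 (0.69), Ube2j2 (0.55) and Plaat3 (0.55). Among those with a lower mean they belonged to the transcription factor gene Msc (-0.93), the ligand gene Wnt7b (-0.69), Wfdc3 (-0.70), Nt5dc2 (-0.62), the neuropeptide gene Calcb (-0.74), the potassium channel gene Kcnc4 (-1.29), H2-Q3 (-0.58) and Brd3os (-0.70). Msc was at 3.51 ± 0.20 in knockout and 4.44 ± 0.04 in floxed ileum, with an adjusted p of 0.573. The other 15 had an adjusted p of 0.711.

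Of the 34 lists, 12 rose and 1 fell in knockout ileum. Again 0 members of these 13 lists were past the threshold over all genes and 0 when adjusted over the list alone. No call held with an estimated correlation (adjusted p = 0.584 for each of the 13 lists with an estimated correlation). With the preset correlation, oxidative phosphorylation had an adjusted p of 6.96e-12, Paneth cell genes 2.18e-05 and smooth muscle genes 2.18e-05. Goblet cell genes (0.000124, 14 of 15 positive) included Zg16 at 0.67, Spink4 at 1.35 and Agr2 at 1.24, and cell cycle genes (0.000124, 22 of 25 positive) included Rrm1 at 0.67 and Mcm5 at 0.58. Glycolysis (0.000501, with Ldha at 0.87), cholesterol synthesis (0.000761, with Idi1 at 0.86), antioxidant enzymes (0.000761), fibroblast and matrix genes (0.00104, with Fn1 at 0.49 and Postn at 0.72), small-intestinal enterocyte genes (0.00176, with the disaccharidase Treh at 0.68 and Ace at 0.52) and the unfolded protein response (0.00814) also rose. The PPARβ/δ target list rose (0.00357, 16 of 20 positive, median 0.34), with Acadl at 1.06, Etfdh at 0.41 and Ucp2 at 0.34, while its member Ucp3 was at -0.45. The difference of its list mean was 0.293, which became 0.141 without ileum knockout 1 and -0.255 (95% interval from -0.748 to 0.239) at equal array background. Genes of the exocrine pancreas, a check for another tissue, fell as a list (0.0382, 13 of 14 negative, median -0.12). Array background averaged 6.229 ± 0.197 in ileum knockout and 6.754 ± 0.266 in ileum floxed arrays (two-sided exact permutation p = 0.1, the smallest possible). The groups did not overlap, with at most 6.379 in knockout and at least 6.599 in floxed arrays. Ileum values at equal background, or with background as a covariate, are therefore extrapolated, and those over both tissues in part. The median of all negative control rows was 2.915 ± 0.055 and 2.920 ± 0.014 (two-sided exact permutation p = 1).

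In limma 0 genes passed in the ileum, with 2079 at an unadjusted p under 0.05 where 1564 were expected by chance, and a smallest adjusted p of 0.551. Another split of the ileum arrays gave 3787 such genes. The 13 lists became 2 without ileum knockout 1, and with array background as a covariate 11 lists passed, all of them lower in the knockout and 6 of them turned from higher to lower. Ileum knockout 1 was at -72.3 on the first principal component, with the others from -35.4 to 43.9. Without ileum knockout 1, the difference of the list mean also went from 0.299 to 0.068 for cell cycle genes, from 0.324 to 0.079 for the unfolded protein response, and from 0.318 to 0.149 for antioxidant enzymes. It went from 0.313 to 0.155 for glycolysis, from 0.329 to 0.188 for cholesterol synthesis, from 0.270 to 0.154 for fibroblast and matrix genes and from -0.139 to -0.062 for exocrine pancreas genes. Without ileum floxed 2 it went from 0.312 to 0.105 for small-intestinal enterocyte genes. It became 0.372 for oxidative phosphorylation, 0.186 for PPARβ/δ targets, 0.194 for antioxidant enzymes, 0.195 for glycolysis, 0.210 for cholesterol synthesis, 0.209 for the unfolded protein response and -0.085 for exocrine pancreas genes. Without that array 9 lists were higher and 1 lower. Leaving out ileum knockout 2 made the difference of the list mean larger, 1.397 for Paneth cell genes in place of 0.919. It was then 0.475 for cell cycle genes, 0.506 for the unfolded protein response and -0.21 for exocrine pancreas genes.

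Over both tissues, with each tissue's difference weighted equally, the knockout minus floxed difference was positive for all 33 oxidative phosphorylation genes (median 0.55, with Sdha at 0.63 and Cox7a2 at 0.74) and for 14 of 15 goblet cell genes (median 0.43, with the gel-forming mucin Muc2 at 0.91, Agr2 at 1.14, Spink4 at 1.07 and Klk1 at 0.83). Txn1, the gene of thioredoxin, was at 8.09 ± 0.48 in knockout and 7.29 ± 0.25 in floxed colon and at 8.07 ± 0.81 and 6.83 ± 0.65 in ileum, a difference over both of 1.02 (adjusted p = 0.462). The genes of smallest p that were higher were Cttnbp2nl (0.49), Psmb2 (0.72), Mospd3 (0.60), Med9 (0.91), Raly (0.70), Bend3 (0.53), Qrich1 (0.77) and Speer9-ps1 (0.66). Those that were lower were Wnt7b (-0.53), Msc (-0.57), Kctd16 (-0.97), Scgb1a1 (-0.54), Wfdc3 (-0.49), Kcnc4 (-0.93), Pou4f3 (-0.48) and Ribc1 (-0.61). All of these had an adjusted p of 0.462. Of the 34 lists, 17 rose and 2 fell, and 0 members of these 19 lists passed over all genes or adjusted over the list alone. None of the 19 calls held with an estimated correlation (adjusted p = 0.419 for each with an estimated correlation). With the preset correlation, oxidative phosphorylation (3.26e-13), goblet cell (1.64e-07), cholesterol synthesis (1.44e-05) and glycolysis, Paneth cell and PPARβ/δ target genes (7.61e-05 each) had the smallest adjusted p-values. The PPARβ/δ target list had 18 of 20 positive members, with Ucp2 at 0.41, Acadl at 0.87, the lipid droplet gene Plin2 at 0.33 and Hadhb at 0.55. The difference of its list mean was 0.308, which became 0.146 without colon knockout 1 and ileum knockout 1 and -0.115 (95% interval from -0.481 to 0.250) at equal array background.

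Markers of other cell types were among the lists that passed over both tissues with the preset correlation and not with an estimated correlation (adjusted p = 0.419 for each). Smooth muscle (0.000108, with Acta2 at 0.81), fibroblast and matrix (0.000532, with Fn1 at 0.44) and myeloid genes (0.0258, with C1qc at 0.37) rose. Exocrine pancreas genes (0.0193, median -0.13) and B and plasma cell genes (0.0279, median -0.18, with Mzb1 at -0.29 and Cd79a at -0.37) fell. Neither fall passed without colon floxed 2 (16 lists higher, 0 lower). The mean of the B and plasma cell list differed by -0.079 (95% interval from -0.358 to 0.199, two-sided exact permutation p = 0.465 within tissue), and by 0.005 without ileum floxed 1. It differed by -0.147 without ileum knockout 1 and -0.134 without ileum floxed 2, and by -0.039 without colon floxed 2 and -0.036 without ileum knockout 3. Over both tissues the knockout arrays had the lower array background, with a two-sided exact permutation p of 0.01 when groups were permuted within tissue, against 0.755 for the median of all negative control rows. The mean of the oxidative phosphorylation list was 0.513 higher in knockout arrays (95% interval from -0.021 to 1.048) and -0.183 (from -0.481 to 0.115) at equal array background. In limma 0 genes passed over both tissues, with 3360 at an unadjusted p under 0.05 where 1564 were expected by chance. Of 100 splits of the arrays within tissue, the real one included, 5 gave at least as many. Without colon knockout 1 and ileum knockout 1 the 19 lists became 9, and with array background as a covariate 4 passed, all lower in the knockout. Without ileum knockout 1 the difference of the list mean went from 0.415 to 0.250 for smooth muscle genes, from 0.697 to 0.410 for Paneth cell genes, from 0.236 to 0.121 for cell cycle genes and from 0.293 to 0.170 for the unfolded protein response. Without colon knockout 1 it went from 0.260 to 0.172 for the antioxidant response, from 0.335 to 0.217 for xenobiotic metabolism and from 0.233 to 0.151 for the interferon response. It was 0.146 for the interferon response without colon floxed 2, and without ileum floxed 2 it went from 0.214 to 0.110 for enterocyte genes.

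**Figure D2:**
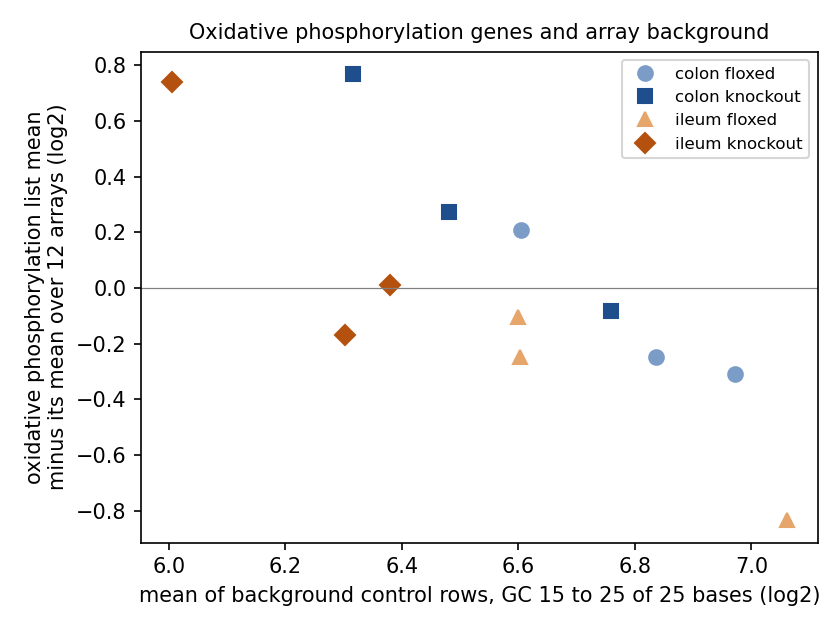
Mean of the oxidative phosphorylation list in each array minus its mean over the 12 arrays (log2, vertical axis) against the mean of that array's background control rows (log2, horizontal axis), with a marker per array and a shape and colour per group. Colon knockout 1 (0.769) and ileum knockout 1 (0.741) had the highest list means and ileum floxed 2 (-0.835) the lowest.

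Whether the knockout difference itself differed between the tissues was tested as an interaction, coded as the colon difference minus the ileum difference. The gene of smallest p on the negative side was Lgals2, galectin-2, at -1.97 with a standard error of 0.46, and on the positive side Calcb at 1.18. The 3 lists of smallest p, none past the threshold, were small-intestinal enterocyte genes (adjusted p = 0.14), smooth muscle genes (0.14) and Paneth cell genes (0.154). Members of the enterocyte list with the smallest p were Ace (-0.56), Treh (-0.59), Mttp (-0.68) and the peptide transporter Slc15a1 (-1.02), of the smooth muscle list Synpo2 (-0.52) and Myh11 (-0.54), and of the Paneth cell list Lyz1 (-1.60) and Reg3a (-1.57). Other genes of smallest p were Mtif3 (1.13), Smbd1 (0.91), Slc10a4l (1.02), Erp29 (0.92), H2-Q3 (0.67), Slc45a4 (0.71) and Spata5l1 (1.32) on the positive side, and Rasl11a (-0.81), Il1f10 (-1.13), G6pc (95% interval from -1.56 to -0.45), Prlhr (-0.95), Pcdhb5 (-0.94), Serpina3g (-1.03) and Obox4-ps27 (-0.91) on the negative side. None passed. In limma 0 genes passed, with 775 at an unadjusted p under 0.05 where 1564 were expected by chance, and every named gene had an adjusted p of 1. Of the 34 lists 0 passed with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.984 with an estimated correlation). Leaving out an array gave 5 lists without colon knockout 3 and without ileum knockout 2, 3 without colon floxed 1, colon floxed 2 or ileum floxed 1, 2 without colon knockout 1, ileum floxed 3 or ileum knockout 3, and 1 without ileum floxed 2 or ileum knockout 1, in no common direction. Array background as a covariate gave 10, all positive. Across genes the colon and ileum differences, which share no arrays, had a correlation of 0.453, in which genes are not independent replicates.

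Colon and ileum mucosa were then compared within each genotype, which asks how the regions differ and checks the tissue labels. In floxed mice Fabp6, the bile acid-binding protein of the ileum, was at 10.56 ± 0.60 in ileum and 3.74 ± 0.54 in colon, 112.77-fold higher (log2 difference 6.82, standard error 0.34, adjusted p = 5.95e-07). Anpep, the brush border aminopeptidase N, was 63.24-fold higher at 10.22 ± 0.47 against 4.24 ± 0.26, and the apolipoprotein gene Apoa1 was 32.90-fold higher at 9.92 ± 0.10 against 4.88 ± 0.24. In the other direction Car1, a carbonic anhydrase of colon epithelium, was at 2.77 ± 0.19 in ileum and 8.96 ± 1.54 in colon (log2 difference -6.19, adjusted p = 0.000126), and Car2 at 3.63 ± 0.27 and 7.86 ± 0.57 (-4.23, adjusted p = 1.49e-05).

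**Figure D3:**
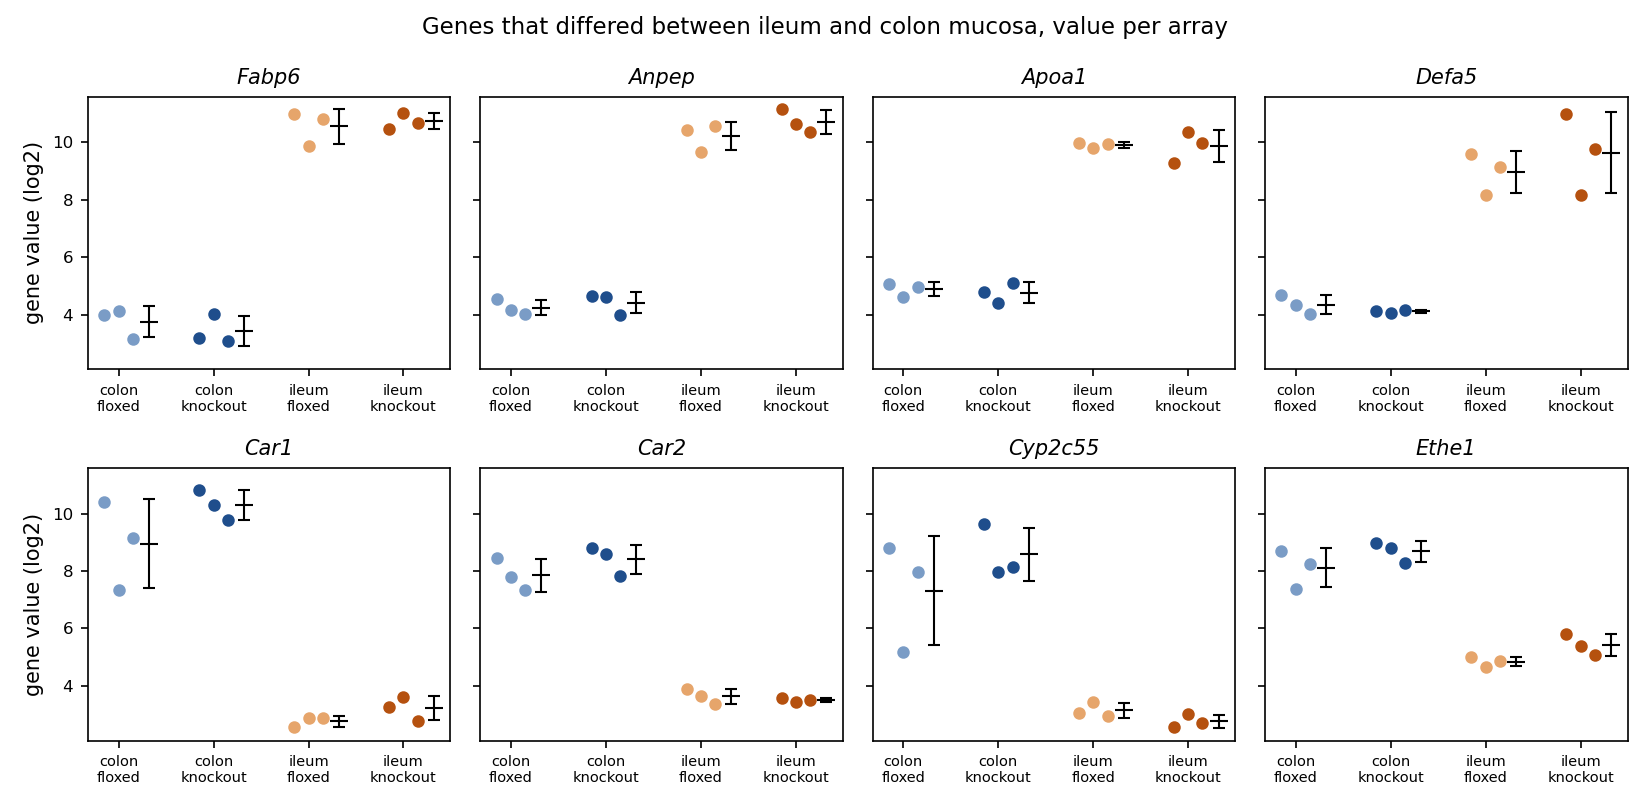
Gene values (log2, vertical axes) of Fabp6, Anpep, Apoa1, Defa5, Car1, Car2, Cyp2c55 and Ethe1 in each array by group (horizontal axes), with dots for the 3 arrays of a group and a cross and bar for their mean ± SD. Fabp6 lay between 9.87 and 11.04 in the 6 ileum arrays and between 3.06 and 4.11 in the 6 colon arrays, and Car1 between 2.55 and 3.60 in ileum and between 7.33 and 10.82 in colon.

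The other genes with the largest rises in floxed ileum were the alpha-defensins Defa30 (5.33, adjusted p = 0.00266), Defa27 (5.22, 0.000267) and Defa5 (4.63, 0.00107), the bactericidal lectin Reg3g (5.08, 0.0285) and the fatty acid-binding protein Fabp2 (4.45, 0.0331). Reg3g and Fabp2 varied among the colon arrays, with means of 6.48 ± 2.27 and 5.13 ± 2.14. Both were lowest in colon floxed 2, so their rises owed part of their size to that array. Reg3g was at 4.1 there against 8.63 and 6.7 in the other floxed colon arrays, and Fabp2 at 2.77 against 6.93 and 5.7. The other largest falls were those of the cytochrome P450 gene Cyp2c55 (-4.18, 0.0147), Ethe1, an enzyme of mitochondrial sulfide oxidation (-3.27, 0.000142), Sycn (-3.16, 0.0234), Klk1 (-3.09, 0.000744), Hao2 (-2.72, 0.00216) and the alcohol dehydrogenase gene Adh1 (-2.62, 0.0455). The falls of Sycn and Adh1 owed part of their size to colon floxed 2. Sycn was at 8.15 in that array against 5.92 and 5.70 in the other floxed colon arrays, and Adh1 at 8.04 against 5.77 and 5.50. Cyp2c55 was lowest in that array, at 5.19 against 8.80 and 7.96. The defensin genes are near-identical copies and the P450 genes of the Cyp2c group are closely related, so array rows could share signal among them, and the value of each single copy is uncertain. Folds against a group near background understate the difference.

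Of 22 small-intestinal enterocyte genes measured, 16 rose in floxed ileum, 0 fell and 6 did not pass, and 18 rose when adjusted over the list alone. Besides Anpep and Apoa1 they included Apob (4.44), the peptidase Enpep (3.86), sucrase-isomaltase, Sis (3.18), the lipid transfer protein Mttp (2.70) and the peptidase Dpp4 (2.72). The list had an adjusted p of 3.87e-55 (0.000703 with an estimated correlation). Of 11 genes of ileal bile acid handling 5 rose and 0 fell, and 7 rose when adjusted over the list alone. They were Fabp6, the vitamin B12 receptor cubilin, Cubn (3.04), the bile acid exporter subunits Slc51a (3.17) and Slc51b (2.58), and Abcc2 (1.19), and the list had an adjusted p of 2.34e-16 (0.0107 with an estimated correlation). Slc51a was at 3.73 in colon floxed 2 against 5.9 and 5.72 in the other floxed colon arrays, so its rise owed part of its size to that array. Of 16 Paneth cell and antimicrobial genes 7 rose, among them Defa5, Defa22 (4.03), Reg3g and the nitric oxide synthase gene Nos2 (2.27), and 10 rose and 1 fell when adjusted over the list alone. The Paneth list had an adjusted p of 2.34e-16, which was lost with an estimated correlation (adjusted p = 0.113 with an estimated correlation).

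The colon epithelium list fell in floxed ileum (adjusted p = 4.28e-10, 0.00215 with an estimated correlation). Of its 21 measured genes 4 fell, namely Car1, Cyp2c55, Sycn and the water channel Aqp8 (-1.73), and 0 rose, against 8 that fell and 1 that rose when adjusted over the list alone. Of 15 goblet cell genes 2 fell, Klk1 and the transcription factor Creb3l1 (-1.76), 5 when adjusted over the list alone, and Retnlb, made by goblet cells, was at -3.02 without passing (adjusted p = 0.086). The goblet cell list fell with an adjusted p of 2.18e-09, lost with an estimated correlation (adjusted p = 0.3 with an estimated correlation).

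Other lists that passed in floxed mice were cholesterol synthesis, tight junctions and MHC class II, which rose in the ileum, and oxidative phosphorylation, glycolysis and fibroblast and matrix genes, which fell. Cholesterol synthesis genes had a median of 0.40 (adjusted p = 6.41e-05, 0.589 with an estimated correlation), and 0 of 14 passed, with Fdft1 at 0.46, Cyp51 at 0.64 and Hmgcs1 at 0.77. Oxidative phosphorylation had a median of -0.27 (0.000239, 0.838 with an estimated correlation) and 0 genes past the threshold. In the glycolysis list the glucose transporter Slc2a1 (-1.01) and the phosphofructokinase Pfkl (-0.75) fell, 2 of 19, with a list median of -0.09 (0.000717, 0.688 with an estimated correlation). Fibroblast and matrix genes had a median of -0.17 (0.000784, 0.599 with an estimated correlation), tight junction genes 0.23 (0.00983, 0.688) and MHC class II genes 0.23 with 10 of 10 positive (0.012, 0.524). None of these last 3 lists had a member past the threshold over all genes. The difference of the list mean was -0.280 for oxidative phosphorylation and -0.255 for glycolysis, and became -0.061 and -0.138 without ileum floxed 2 and -0.118 and -0.146 without colon floxed 1. For tight junctions it went from 0.228 to 0.125 without colon floxed 2 and to 0.357 without colon floxed 1. For oxidative phosphorylation it was -0.426 without ileum floxed 3. Outside the lists that passed, Olfm4, a gene of crypt base stem cells, rose (1.57), and the glutathione transferase Gstm1 (-2.01), Prdx6 (-1.14) and the sulfotransferase Sult1a1 (-1.61) fell.

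In limma 184 of 31276 genes passed in floxed mice, 124 higher and 60 lower in ileum. The count was 119 without colon floxed 2, 116 without colon floxed 3, 94 without ileum floxed 1 and 93 without ileum floxed 3. It was 334 (207 higher and 127 lower) with array background as a covariate and 280 (193 higher and 87 lower) with array weights, and taking each gene's brightest row turned the split to 62 higher and 143 lower, with 58 of these genes among the 184. For the mean of each of the enterocyte, bile acid, Paneth, colon epithelium and goblet lists the 3 ileum arrays did not overlap the 3 colon arrays, with a two-sided exact permutation p of 0.1, the smallest possible.

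In knockout mice Fabp6 was at 10.74 ± 0.28 in ileum and 3.42 ± 0.51 in colon, 159.39-fold higher (log2 difference 7.32, standard error 0.34, adjusted p = 3.72e-07), and Anpep at 10.72 ± 0.41 and 4.42 ± 0.36, 78.74-fold higher. Lgals2, galectin-2, was 57.49-fold higher in ileum at 8.99 ± 0.78 against 3.14 ± 0.41 (adjusted p = 1.45e-06). Car1 was at 3.22 ± 0.41 in ileum and 10.30 ± 0.52 in colon (log2 difference -7.08, adjusted p = 2.96e-05), and Cyp2c55 at 2.76 ± 0.24 and 8.59 ± 0.92 (-5.83, adjusted p = 0.000886).

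The other largest rises in knockout ileum were all of defensin genes, Defa30 (6.27), Defa27 (6.21), Defa5 (5.54), Defa41 (5.34) and the pseudogene Defa-ps6 (5.22). The other largest falls were those of Car2 (-4.89), Hao2 (-3.70), Ethe1 (-3.25), Klk1 (-3.08), Cyp2c65 (-2.99, adjusted p = 0.0494) and Sycn (-2.99, adjusted p = 0.0266). Single defensin and Cyp2c copies are uncertain here as in floxed mice.

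Of 22 small-intestinal enterocyte genes 17 rose in knockout ileum, 0 fell and 5 did not pass, and 19 rose when adjusted over the list alone, with Apoa1 at 5.12, Apob at 4.58, Enpep at 4.52 and Slc15a1 at 3.03 (list adjusted p = 8.64e-57, 0.00063 with an estimated correlation). Of 11 bile acid genes 5 rose, 7 when adjusted over the list alone, with Cubn at 2.56 and Abcc2 at 1.29 (list adjusted p = 1.77e-16, 0.0104 with an estimated correlation). Of 16 Paneth cell genes 7 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone. Defa22 (5.07), Nos2 (2.93), Lyz1 (3.65) and Reg3a (3.71) rose, and guanylin, Guca2a, a peptide that goblet cells also make, fell (-1.66, adjusted p = 0.0365). The Paneth list had an adjusted p of 2.03e-19, lost with an estimated correlation (adjusted p = 0.0715 with an estimated correlation). Of 21 colon epithelium genes 3 fell, Car1, Cyp2c55 and Sycn, and 9 fell and 1 rose when adjusted over the list alone (list median -0.41, adjusted p = 8.22e-08, 0.00569 with an estimated correlation). Of 15 goblet cell genes 2 fell, Klk1 and Creb3l1 (-1.99), 8 when adjusted over the list alone, with Retnlb at -2.99 (adjusted p = 0.0715). The goblet cell list had an adjusted p of 9.88e-10 (adjusted p = 0.228 with an estimated correlation).

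In knockout mice the smooth muscle list rose in ileum (median 0.62, 10 of 11 positive, adjusted p = 9.12e-06, 0.489 with an estimated correlation) with 0 members past the threshold, among them Mylk at 0.63, Myh11 at 0.88 and Cnn1 at 0.84. Cell cycle (0.000332), cholesterol synthesis (0.000754), inflammatory (0.039) and endothelial genes (0.039) rose as lists, and glycolysis (0.00895), xenobiotic metabolism (0.0308), fibroblast and matrix (0.0398) and antioxidant response genes (0.0495) fell. With an estimated correlation the adjusted p was 0.228 for the inflammatory list, 0.424 for the endothelial list and 0.617 for each of the other 6. Members that passed were Idi1 (1.22) in cholesterol synthesis, Nos2 in the inflammatory list, Pfkl (-0.86), Slc2a1 (-0.87) and Hk1 (-0.74) in glycolysis, Sult1a1 (-2.10), Adh1 (-2.56) and Cyp2c65 in xenobiotic metabolism, and in the antioxidant response list Gstm1, which fell (-2.11), and Abcc2, which rose (1.29). Idi1 was dim, at 2.2 in knockout colon and 3.42 in knockout ileum, where the medians of negative control rows were 2.924 and 2.915. Without ileum knockout 1 the difference of the list mean went from 0.6 to 0.271 for smooth muscle genes, from 0.241 to 0.009 for cell cycle genes, from 0.330 to 0.197 for inflammatory genes and from 0.395 to 0.255 for cholesterol synthesis. Without colon knockout 1 it went from -0.245 to -0.069 for the antioxidant response, from -0.415 to -0.180 for xenobiotic metabolism, from -0.193 to -0.084 for glycolysis and from -0.130 to -0.039 for fibroblast and matrix genes. Without colon knockout 3 it was 0.122 for cell cycle genes. Without ileum knockout 2 and without ileum knockout 3 it was -0.122 and -0.107 for glycolysis and -0.065 and -0.080 for fibroblast and matrix genes. Other omissions made it larger in size. Without colon knockout 3 it was -0.409 for the antioxidant response, -0.643 for xenobiotic metabolism, -0.308 for glycolysis and -0.226 for fibroblast and matrix genes. Without ileum knockout 1 these were -0.402 for the antioxidant response, -0.351 for glycolysis and -0.246 for fibroblast and matrix genes. Cell cycle genes were at 0.417 without ileum knockout 2 and 0.371 without colon knockout 1. Outside these lists Olfm4 rose (2.39) and the transcription factor Sox9 fell (-0.70).

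In limma 247 genes passed in knockout mice, 150 higher and 97 lower in ileum. The count was 135 without colon knockout 2, 163 without ileum knockout 3 and 144 without colon knockout 1 and ileum knockout 1 together, and the 14 lists, 8 higher and 6 lower, became 9 (7 higher and 2 lower) without ileum knockout 3 and 16 (5 higher and 11 lower) without ileum knockout 1. With array background as a covariate 415 genes passed, 139 higher and 276 lower, and taking each gene's brightest row gave 79 higher and 136 lower, with 76 of these genes among the 247. As in floxed mice, the means of the 5 regional lists did not overlap between ileum and colon arrays (two-sided exact permutation p = 0.1, the smallest possible).

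**Figure D4:**
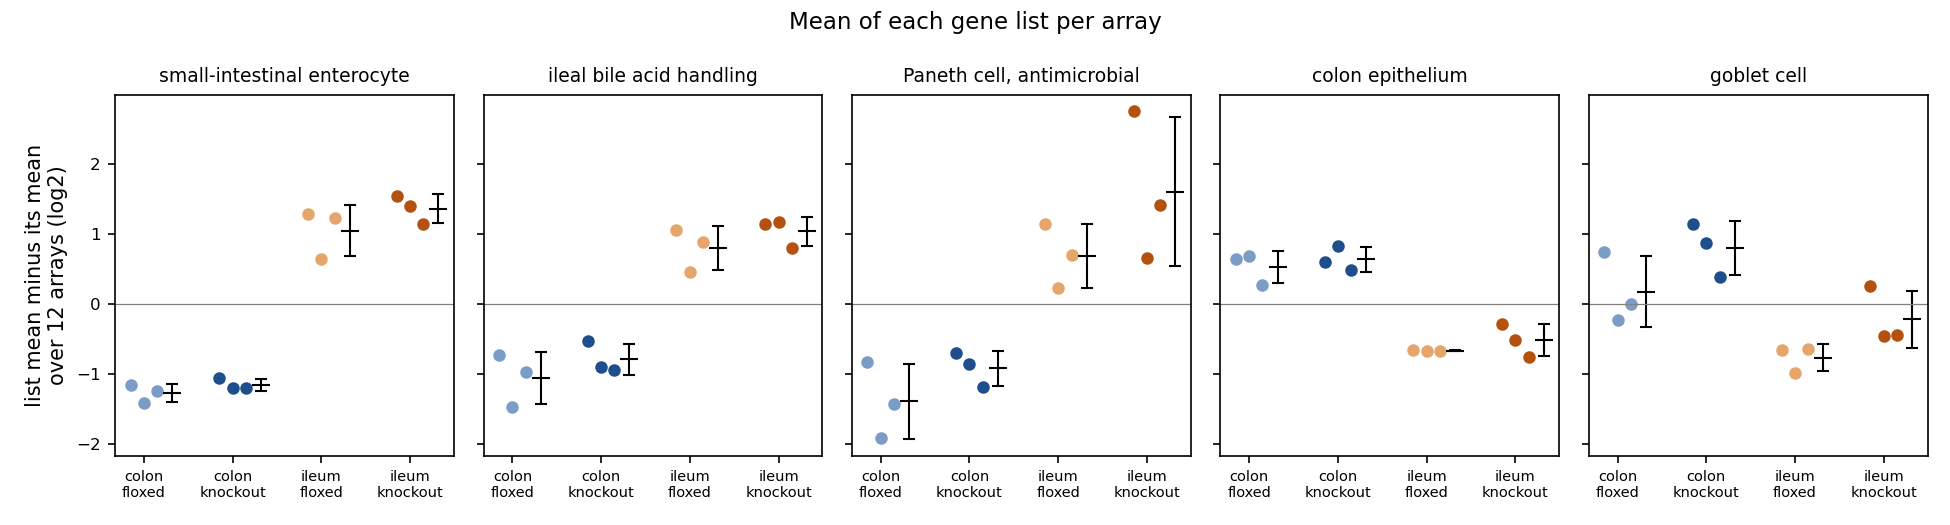
Mean of 5 gene lists in each array minus that list's mean over the 12 arrays (log2, vertical axis) by group (horizontal axes), with dots for the 3 arrays of a group and a cross and bar for their mean ± SD. The small-intestinal enterocyte list averaged 1.054 ± 0.360 in floxed ileum, 1.366 ± 0.206 in knockout ileum, -1.268 ± 0.129 in floxed colon and -1.152 ± 0.086 in knockout colon.

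The regional difference involved shared genes in both genotypes. Of the genes higher in ileum, 124 in floxed and 150 in knockout mice, 103 were shared, where independent lists would share 0.595, and of the genes lower in ileum, 60 and 97, 45 were shared, where independent lists would share 0.186. All 124 genes that rose in floxed ileum had the same sign in knockout mice, and 59 of the 60 that fell did. The compared group means have no arrays in common, but the calls of both genotypes used the same estimate of each gene's spread from all arrays. The calls are therefore not independent. Across genes their differences had a correlation of 0.634, in which genes are not independent replicates. That a gene passed in only 1 genotype does not show a difference between genotypes, since 0 genes passed the interaction test in limma, with 775 at an unadjusted p under 0.05.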

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

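The test of array rows that carry no gene symbol was chosen after the tables had been seen. Among the 120210 rows without a symbol, which enter no gene value, 98 differed between ileum and colon in floxed mice, 60 of them higher and 38 lower in ileum, and 140 differed in knockout mice, 91 higher and 49 lower, in limma at an adjusted p of 0.05 over all 719071 rows. No comparison of genes uses these rows. Of all 719071 rows, 2051 passed in floxed and 2737 in knockout mice, and the shares were not compared by a test. Over both genotypes 340 such rows passed, 202 higher and 138 lower in ileum. Between knockout and floxed mice 0 rows passed in limma, with or without a symbol, while 35899 of all rows in the colon and 52406 in the ileum had an unadjusted p under 0.05. No explanation was tested for these rows.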

How the results depend on the processing

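Settings with array background as a covariate, with probe selection regions only, with both first knockout or both second floxed arrays left out, and the omission of arrays for the lists were added after the data were seen, and the other settings were planned. Between knockout and floxed mice 0 genes passed under every setting run for the colon, for both tissues and for the interaction, leaving out arrays included (0 to 0), and for the ileum under all but the replicate block, which gave 1 gene, lower in the knockout. The genes that passed in ileum vs colon, floxed, numbered 280 with array weights and 334 with the background covariate, and 93 to 191 with an array left out. In ileum vs colon, knockout, they numbered 415 with the background covariate, 144 without both first knockout arrays, and 135 to 190 with an array left out. With an estimated correlation the gene lists, knockout vs floxed, colon, fell from 13 to 0, those of the ileum from 13 to 0, those over both tissues from 19 to 0, those of ileum vs colon, floxed, from 11 to 3 and those of ileum vs colon, knockout, from 14 to 3. The brighter part of the genes left 8 lists in the colon and gave 3 in the interaction. The background covariate left 1 list in the colon and 4 over both tissues, gave 10 in the interaction, and turned 6 of the lists of the ileum and 3 of those over both tissues to the opposite direction. Without both first knockout arrays 3 lists passed in the colon, 6 in the ileum, 9 over both tissues and 9 in ileum vs colon, knockout, without both second floxed arrays 8 passed in the colon, and with probe selection regions only 2 passed in the interaction. With an array left out the lists numbered 3 to 17 in the colon, 2 to 16 in the ileum, 16 to 20 over both tissues, 0 to 5 in the interaction, 9 to 13 in ileum vs colon, floxed, and 9 to 16 in ileum vs colon, knockout. No named gene reversed its direction while called. Of the values of named genes under these settings, 40 were lost and 7 gained in floxed and 24 lost and 6 gained in knockout mice between regions, and none changed its call between genotypes. The cause was not tested, except that fewer arrays leave fewer degrees of freedom.

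The replicate block gave 232 genes in ileum vs colon, floxed, 332 in ileum vs colon, knockout, 1 in knockout vs floxed, ileum, and 14 lists in the colon, 14 in the ileum, 19 over both tissues and 3 in the interaction, and these last and the 1 gene were the counts it moved by more than 1.5 times. Among named genes Retnlb passed between regions under the block in both genotypes (-3.02 and -2.99), and no other named gene changed its call. Arrays with the same number did not deviate together in every pair, since the correlation of their deviations was 0.31, 0.07 and 0.26 between knockout and floxed colon, 0.33, 0.38 and -0.18 between knockout and floxed ileum, 0.53, -0.05 and 0.22 between colon and ileum of knockout mice, and 0.26, 0.10 and -0.13 of floxed mice, and not every array correlated best with its own number, so the numbers were not taken as pairs.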

Other observations

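The families of genes, the regional contrast over both genotypes and the tests at equal array background were chosen after the results had been seen, as were the permutation test of genotype on the list mean and the count of risen lists against matched random lists, while the random lists for oxidative phosphorylation and smooth muscle, the omission of first knockout arrays and the splits of the arrays were set before their results. Families were read from symbol prefixes, 19 in all, and tested in ileum against colon over both genotypes, where 566 genes passed in limma, 322 higher and 244 lower in ileum. Prefixes can match genes outside a family, such as Apobec genes among the apolipoproteins, Slc9a3r1 among the solute carriers and kinase genes among the ribosomal proteins. Counts, medians and p-values of families therefore describe sets of symbols, chosen after regional genes had been seen. The solute carriers did not pass as a family (adjusted p = 0.186, 0.498 with an estimated correlation, median 0.001). Of 371 solute carriers 38 rose and 13 fell, with the neutral amino acid transporter Slc6a19 at 2.65, the nucleoside transporter Slc28a2 at 3.09, the phosphate transporter Slc34a2 at 2.86, the sulfate transporter Slc13a1 at 2.95, the cystine transporter subunit Slc7a9 at 2.20 and the bile acid transporter Slc10a2 at 2.24, while the sodium-proton exchanger Slc9a3 (-1.68) and the chloride-bicarbonate exchanger Slc26a3 (-1.26) fell. The set of aminopeptidases and dipeptidases was put together from named symbols, among them Anpep, Enpep and Dpp4, which had already been seen to rise. Of its 13 genes 7 rose, among them Naaladl1 (4.48), Enpep (4.19), Xpnpep2 (2.48) and Cndp2 (1.82), with an adjusted p of 1.02e-22 (0.003 with an estimated correlation). This p-value is therefore no independent support for the family. Of 17 genes with symbols that begin like those of apolipoproteins 5 rose, with Apoa4 at 3.08 and Apoc2 at 1.61 (4.82e-08, 0.003 with an estimated correlation, median 0.042).

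Of 26 alpha-defensin genes and pseudogenes 19 rose in ileum (median 2.92, adjusted p = 4.23e-45, 0.00561 with an estimated correlation), with single copies uncertain because of their similarity, and of 7 regenerating protein genes Reg3g (4.51) and Reg3a (2.92) rose (7.11e-06, 0.00561 with an estimated correlation). Of 20 glutathione transferases 3 fell, Gstm1 (-2.06), Gstm2 (-0.92) and Gstm3 (-1.05), and the family's adjusted p of 4.72e-08 was 0.0623 with an estimated correlation. Of 20 UDP-glucuronosyltransferases Ugt1a6a fell (-1.36, family adjusted p = 2.96e-05, 0.0291 with an estimated correlation), and of 16 carbonic anhydrases Car1 (-6.64) and Car2 (-4.56) fell (6.19e-05, 0.0309 with an estimated correlation). Of 36 Hox genes Hoxa11 fell (-0.90, family adjusted p = 0.000101, 0.257 with an estimated correlation). Among mucins the gel-forming Muc2 (-1.69) and the membrane-bound Muc4 (-1.08) fell and the membrane-bound Muc13 rose (1.54). Between knockout and floxed mice over both tissues, 276 ribosomal protein genes and pseudogenes had a median of 0.459 with 0 genes past the threshold in limma (family adjusted p = 1.75e-19, 0.563 with an estimated correlation). In the same comparison the Hox genes had a median of -0.18 (0.00234, 0.563 with an estimated correlation) and the glutathione transferases 0.203 (0.046, 0.694 with an estimated correlation), so no family passed there with an estimated correlation.

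Lists of bright genes were higher in knockout mucosa, although none of the 19 calls held with an estimated correlation (adjusted p = 0.419 for each with an estimated correlation), and array background, measured in control rows rich in G and C, is a candidate explanation, while the median of all negative control rows showed no such difference beyond its spread (two-sided exact permutation p = 0.755 within tissue). At equal background the oxidative phosphorylation difference over both tissues went from 0.513 (95% interval from -0.021 to 1.048) to -0.183 (from -0.481 to 0.115), and of the 17 lists that rose 3 had an interval above 0 before and 0 at equal background, because the differences moved from 0.164 to 0.697 down to -0.209 to 0.002 and not because their intervals widened. Against random lists matched on brightness, oxidative phosphorylation lay at percentile 100, and 13 of the 17 lists lay above the upper bound. The other 4 (fibroblast, myeloid, glycolysis and tight junction genes) lay inside, with medians from 0.113 to 0.218 against matched medians from -0.001 to 0.185. Genes of the random lists do not move together as those of a pathway do, so their bounds are too narrow. A shift of all bright genes is therefore not excluded for any list. A rise with brightness was present over all genes, taken in deciles of mean gene value. The median knockout minus floxed difference over both tissues was -0.067 in decile 1, the dimmest, and 0.233 in decile 10, the brightest. In decile 10 it was 0.275 in the colon and 0.196 in the ileum. Also open is the weight of the first knockout arrays, without which 9 of 19 lists passed. Genotype itself stays open too. The oxidative phosphorylation list mean had a two-sided exact permutation p of 0.04 within tissue, but genotype cannot be told apart from background in arrays whose background differs by group. The control rows also come from the same processed values as the genes, so the loss of a difference at equal background may be built in to some degree.

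Smooth muscle genes were higher as a list in ileum knockout mucosa, a call that did not hold with an estimated correlation (adjusted p = 0.584 with an estimated correlation) and in which 0 of 11 members passed in limma, and muscle cut along with the mucosa of a single sample could give such a pattern, although that was not tested apart from the array. Without ileum knockout 1 the adjusted p of the list went from 2.18e-05 to 0.0582 and its mean difference from 0.581 (95% interval from -0.141 to 1.302) to 0.251 (from -0.339 to 0.841), so the call ended because the difference shrank. At equal array background the difference was -0.152 (from -0.831 to 0.527), an extrapolation, since ileum knockout and floxed arrays did not overlap in background. The list lay at percentile 100 of matched random lists, but their genes do not move together, so this percentile cannot exclude a shift of all bright genes. Such a shift, the first ileum knockout array and array background remain open, and genotype is not excluded.

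Other splits of the arrays bear on whether chance can be excluded. With 6 arrays there are 10 splits, too few for a share under 0.05. For genes the real split gave 0 in the colon and 0 in the ileum, a count that all 10 of 10 splits reach by construction (highest other 1 in each, with 1494 and 2079 genes at an unadjusted p under 0.05 in limma), so these splits say nothing about chance. It gave 184 in floxed mice between regions (1 of 10, highest other 0) and 247 in knockout mice (1 of 10, highest other 1). For lists it gave 13 in the colon (5 of 10, highest other 18), 13 in the ileum (6 of 10, highest other 21), 11 between regions in floxed mice (4 of 10, highest other 20) and 14 in knockout mice (4 of 10, highest other 19). The 0 genes of both tissues and of the interaction are likewise reached by all 100 of 100 splits within tissue (highest other 1 in each), which says nothing about chance. Of these 100 splits, 5 gave at least the 3360 genes at an unadjusted p under 0.05 (highest other 7505), and 15 gave at least the 19 lists (highest other 23), so chance was not excluded for either over both tissues. For the regional contrast over both genotypes, 1 of 100 splits, the real one, gave 566 genes and the highest other gave 2, so chance was excluded there.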
